A study of Homo sapiens with 16 samples.

How the data were processed

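YY1 ChIP-seq was analysed from 6 peak lists, 1 per library, of untreated, PDS and TMPYP4 293T cells with 2 libraries each. A combined list was also used. It was taken to be of untreated cells because its peak names carry no compound, like those of the untreated lists. Groups and replicate numbers came from the sample titles. The submitters' processing notes name Bowtie2, BWA and MACS2 and the build hg19, without roles or versions. Peak names in the deposited files follow MACS2 numbering on a Bowtie2 alignment, with 1 list per library, so peaks were called in each library separately. The threshold, duplicate handling and control used are not given in the sources used here. How the combined list was made is likewise not given.

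Each deposited peak list has 10 columns. The deposited score was equal to 10 times the -log10 q, reduced to a whole number, in every peak. The deposited fold enrichment is the ratio of the peak to the caller's background, and whether that background came from the same library or a control is not given in the sources used here. The deposited -log10 p-value and -log10 q-value are those of the authors' caller for each peak, and the lowest -log10 q in any list was near that of a q-value of 0.05. These are the authors' own values per peak, and were used only to describe, rank or filter peaks within a list. The deposited summit offsets were not used. Among peaks with -log10 p between 9 and 11, the median fold was 5.41 and 6.80 in untreated replicates 1 and 2, 2.77 and 6.81 in PDS, and 3.44 and 6.80 in TMPYP4. The fold at like significance was thus nearly equal in the 3 libraries of number 2 and differed between those of number 1. Read depth per library is unknown, so no interval for depth was given.

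Peaks of all 6 lists were merged into loci where they overlapped by at least 1 bp, which gave 14573 loci. Coordinates are 1-based hg19. A locus was present in a library when at least 1 of its peaks came from that list. Log2 ratios of peak numbers were tested with two-sided exact permutation tests over the 6 assignments of 2 libraries against 2, which cannot go below p = 0.333. Shares of loci have Wilson 95% intervals, which cover counting error over loci; loci are not replicates. Counts of loci are given with those of the other splits of the same 4 libraries. Untreated strength of a locus was its mean percent rank by -log10 q over both untreated lists. Chance overlap came from 100 circular shifts. Absence by chromosome and by peak width was tested with exact tests stratified by strength decile, with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons at equal length used the strongest 1732 peaks of each list, the length of the shortest.

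The rule for named loci, fixed before the data were examined, took the 10 strongest untreated loci, per compound the 10 strongest in both untreated and neither treated list and the 10 strongest the other way round, and the 5 strongest each way between compounds, on chromosomes 1 to 22 and X. The alternatives fixed at that time were a stricter score, chromosomes 1 to 22 and X only, and each library left out in turn. Also fixed then were 50% reciprocal overlap, merging within 500 bp, equal list length and the replicate number as a block. For the overlap between libraries, a cut to 50% of the shortest list was fixed too. The Kruskal-Wallis (under each setting), chromosome and width tests and the other splits of the 4 treated libraries were added after the data were seen. So were, under other settings, the counts between compounds and the share of loci missing after both. The count of loci missing after both under other settings was planned.

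The reference tables used here name another assembly than hg19 and no hg19 genome or annotation was used, so loci are given by coordinates without genes. Promoter shares, guanine quadruplex and YY1 motif shares and gene lists, which had been planned, were not analysed here. The 2 ChIP control and 8 HiChIP libraries were not analysed here.

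The locus step was tested on simulated lists of 3000 places with 200 missing from both PDS lists, and 200 were found. The places lay far apart and were otherwise in every list. The test therefore checked only the counting, and not how missed peaks affect the counts. The chromosome test was tested on presence drawn for the 4572 untreated loci: with no effect 3.85% of tests gave p under 0.05, and at an odds ratio of 3 on chromosome 7 the share was 98.5%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.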

Results

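The series measured binding of YY1, a zinc-finger transcription factor that also takes part in looping between enhancers and promoters, in 293T cells. This human embryonic kidney line expresses the SV40 large T antigen, and here it carried YY1 with a TAP (tandem affinity purification) tag. Chromatin bound by tagged YY1 was recovered with an anti-Flag antibody and sequenced (ChIP-seq). Cells were left untreated or received PDS (pyridostatin) or TMPYP4 (a cationic porphyrin) for 12 h. Both compounds bind guanine quadruplexes, stacked structures formed by guanine-rich DNA, so the comparisons ask whether these ligands alter where YY1 is found. Each of the 3 groups had 2 libraries, numbered 1 and 2. The 2 ChIP control libraries and 8 HiChIP libraries of the series were not analysed here. No label states that the libraries came from separate cultures, so p-values of the group comparisons measure only the spread between these libraries, which may be technical. The number of reads per library is unknown.

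YY1 peaks were most numerous in untreated cells and least numerous after PDS. The untreated lists held 12958 and 5058 peaks, a mean of 9008 ± 5586 (SD, n = 2). The TMPYP4 lists held 3751 and 4423 peaks (4087 ± 475, SD, n = 2) and the PDS lists 1732 and 3145 (2438.5 ± 999, SD, n = 2), as the plot of peak numbers shows. Median peak widths lay between 155 and 187 bp, and the lists covered from 0.342 Mb in PDS replicate 1 to 2.97 Mb in untreated replicate 1. Across the 3 groups, an exact Kruskal-Wallis test added after the data were seen gave p = 0.0667 (6 of 90 assignments). At a score of at least 82 the untreated and TMPYP4 lists no longer separated, with 2410 peaks in TMPYP4 replicate 1 and 1435 in untreated replicate 2. The PDS lists stayed the shortest, with 871 and 593 peaks against 1077 in TMPYP4 replicate 2. The exact p of the same test was 0.2.

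**Figure D1:**
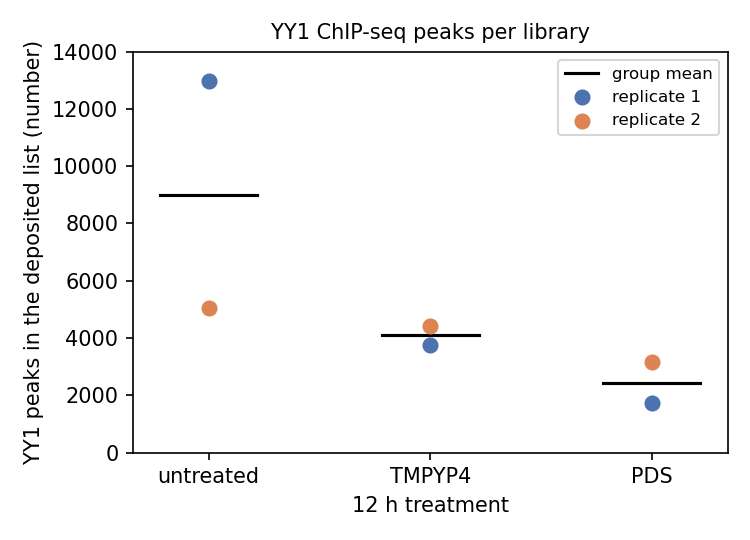
Number of YY1 peaks in each deposited list (y axis) by treatment (x axis), with 1 point per library coloured by replicate number and a black line at the mean of the 2 libraries. The untreated libraries lie at 12958 and 5058 peaks, the TMPYP4 libraries at 3751 and 4423, and the PDS libraries at 1732 and 3145.

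In untreated cells, peaks of both libraries met at 4572 loci, where a locus is a merged interval of overlapping peaks from the 6 lists. The strongest locus by mean rank over both untreated lists was on chromosome 18 at 47813907-47814700 (hg19), with -log10 q of 102 in replicate 1 and 57.0 in replicate 2. It was followed by chromosome 6 at 33756703-33757149 (102 and 55.6), chromosome 1 at 1167066-1168106 (99.2 and 56.3), chromosome 5 at 134209768-134210263 (105 and 49.0) and chromosome 16 at 23160677-23161179 (90.7 and 57.0). The next 5 lay on chromosome 7 at 42951520-42951885, chromosome 1 at 203764548-203764906, chromosome 5 at 147763240-147763673, chromosome 3 at 123303594-123304587 and chromosome 3 at 45429892-45430277. All 10 were listed in each of the 4 treated libraries. Of the 4572 loci, 564 (12.3%) were on chromosome 1 and 315 (6.89%) on each of chromosomes 2 and 19. Of the loci in untreated replicate 2, 92.8% were found in replicate 1, while 35.5% of those in replicate 1 were found in replicate 2. Lists shifted around the chromosomes 100 times overlapped at most 0.415% of loci. A further 7097 loci were in untreated replicate 1 and in no other list.

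After PDS, the strongest untreated loci were mostly still listed and the weaker ones mostly were not. These loci were chosen and ranked by the untreated lists themselves, so a further untreated library could also miss some of them. Of the 4572 loci, 939 (20.5%, Wilson 95% interval 19.4 to 21.7) were in both PDS lists and 1650 (36.1%, 34.7 to 37.5) in neither; the intervals cover counting error over loci only. Among the strongest 915 loci 0.874% were in neither PDS list, against 69.6% among the weakest 915. PDS replicate 1 held 23.9% of the 4572 loci and PDS replicate 2 held 60.5%, a mean of 42.2% ± 25.9 (SD, n = 2). The strongest loci in neither PDS list were chromosome 9 at 6015456-6015762, chromosome 5 at 52856405-52856650, chromosome 16 at 2918154-2918594, chromosome 7 at 27200651-27200840 and chromosome 1 at 52499241-52499528. At the first of these, -log10 q was 48.3 and 12.2 in the untreated libraries and 30.6 and 9.10 in the TMPYP4 libraries. The next 5 were chromosome 12 at 98897234-98897714, chromosome 10 at 103347989-103348258, chromosome 12 at 8395410-8395611, chromosome 14 at 74551559-74551816 and chromosome 3 at 111697801-111698155. Of these 10 loci, 9 were in both TMPYP4 lists.

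Only 4 loci were in both PDS lists and neither untreated list. They were chromosome 21 at 9825804-9826285 and 3 places on chromosome Y, at 58827144-58827437, 58856000-58856331 and 58875191-58875620. At the chromosome 21 locus -log10 q was 3.85 in PDS replicate 1 and 1.70 in PDS replicate 2. The second is close to the lowest value in that list, 1.34. On chromosome Y the values were 28.4 to 54.9 in replicate 1 and 2.88 to 5.96 in replicate 2. The named-locus rule covers chromosomes 1 to 22 and X, so the chromosome Y loci were named after their values were seen. Whether the reads placed at these 3 places came from chromosome Y was not tested. PDS replicate 1 differed from the other lists in composition: 18.9% of its peaks lay off chromosomes 1 to 22 and X, against 0.452% to 1.17% in the other 5 libraries.

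The log2 ratio of peak numbers, PDS against untreated, was -1.79 (SE 0.80), with an exact two-sided permutation p of 0.333, the smallest that 2 libraries against 2 can give. Within replicate number 1 it was -2.90 (7.48-fold fewer peaks) and within number 2 it was -0.69 (1.61-fold fewer). Splitting the same 4 libraries by replicate number gave 177 and 75 loci found in 1 pair only, and the remaining split gave 141 and 0, against 1650 and 4 for the real groups. The real groups set the 2 longest of these lists against the 2 shortest, so the larger count can follow from list length alone. The other splits were not made at equal length. Requiring a score of at least 82 gave 620 loci in neither PDS list, and 1732 peaks per list gave 87, with 15 loci in both PDS lists only. Without untreated replicate 2 the count of 1650 became 9635 and without PDS replicate 2 it became 3478, while the count of 4 became 82 without PDS replicate 1 and 444 without PDS replicate 2. The share of 20.5% became 56.9% at 1732 peaks per list, 7.31% without untreated replicate 2 and 60.5% without PDS replicate 1, and the log2 ratio was -1.12 without untreated replicate 1.

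**Figure D2:**
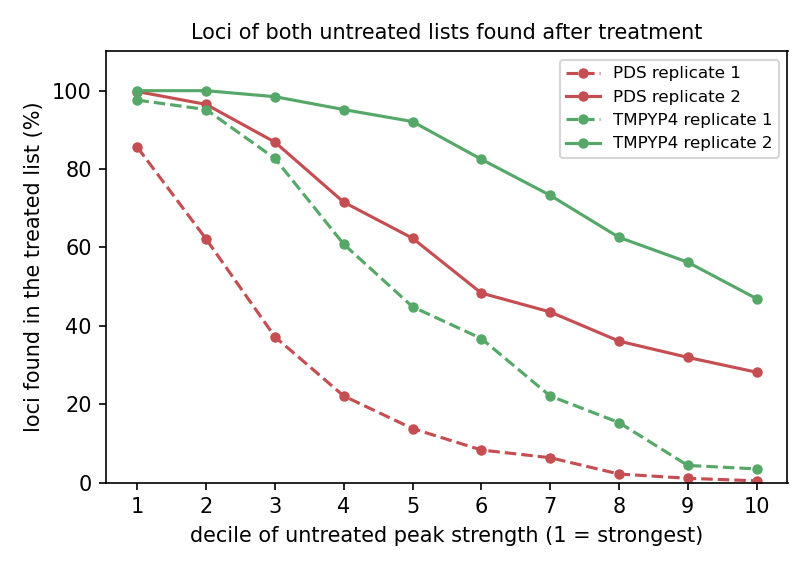
Percent of the loci of both untreated lists found in each treated list (y axis) by decile of untreated peak strength (x axis, 1 strongest), with 1 line per treated library and dashed lines for replicate 1. The share falls from 85.6% to 0.437% in PDS replicate 1, from 99.8% to 28.2% in PDS replicate 2, from 97.6% to 3.49% in TMPYP4 replicate 1 and from 100% to 46.9% in TMPYP4 replicate 2.

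After TMPYP4, more of the untreated loci were listed than after PDS, again with the weakest loci missing most often. Here too the loci were chosen and ranked by the untreated lists themselves. Of the 4572 loci, 1965 (43.0%, Wilson 95% interval 41.6 to 44.4) were in both TMPYP4 lists and 728 (15.9%, 14.9 to 17.0) in neither, and 0 loci were in both TMPYP4 lists and neither untreated list. Among the strongest 915 loci 0% were in neither TMPYP4 list, against 46.7% among the weakest 915. TMPYP4 replicate 1 held 46.3% of the loci and replicate 2 held 80.7%, a mean of 63.5% ± 24.3 (SD, n = 2). The strongest loci in neither TMPYP4 list were chromosome 5 at 134260197-134260318 (-log10 q of 29.7 and 10.7 in the untreated libraries), chromosome 1 at 168025561-168025705, chromosome 7 at 134331529-134331685, chromosome 6 at 147178711-147178857 and chromosome 3 at 52444015-52444136. The next 5 were chromosome 7 at 100291813-100292076, chromosome 7 at 77325708-77325945, chromosome 14 at 24685122-24685383, chromosome 16 at 29465506-29465939 and chromosome 7 at 135194616-135195078. All 10 were also missing from both PDS lists.

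The log2 ratio of peak numbers, TMPYP4 against untreated, was -0.99 (SE 0.69), with an exact two-sided permutation p of 0.333, again the smallest possible. Within replicate number 1 it was -1.79 (3.45-fold fewer peaks) and within number 2 it was -0.19 (1.14-fold fewer). The split of the same 4 libraries by replicate number gave 753 and 103 loci found in 1 pair only, as large as the 728 and 0 of the real groups, and the remaining split gave 330 and 5. The count of 728 became 139 at a score of at least 82 and 43 at 1732 peaks per list, where 31 loci were in both TMPYP4 lists only. Without untreated replicate 2 it became 7909 and without TMPYP4 replicate 2 it became 2454; the count of 0 became 41 without untreated replicate 1, 3 without untreated replicate 2, 112 without TMPYP4 replicate 1 and 778 without TMPYP4 replicate 2. The share of 43.0% became 72.4% at 1732 peaks per list, 15.6% without untreated replicate 2 and 80.7% without TMPYP4 replicate 1, and the log2 ratio was -0.31 without untreated replicate 1 and -1.67 without untreated replicate 2.

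Set against each other, more untreated loci were listed after TMPYP4 and missing after PDS than the reverse. Of the 4572 untreated loci, 239 were in both TMPYP4 lists and neither PDS list, and 2 were the other way round, on chromosome X at 48555115-48555314 and chromosome 1 at 37980195-37980445. Within replicate number 1, 1027 of these untreated loci were in the TMPYP4 list and not the PDS list and 3 the other way round; within number 2 the counts were 1028 and 104. Over all loci the within-number counts were 2394 and 413 (number 1) and 1476 and 263 (number 2). By construction, the gap between such counts equals the gap in the loci that the 2 lists hold. The TMPYP4 and PDS lists held 3698 and 1717 loci in number 1 and 4280 and 3067 in number 2, so these counts restate list length. Splitting the 4 treated libraries by replicate number gave more. Of the untreated loci, 1058 were in both number 2 lists and neither number 1 list, and 33 the other way round. The remaining split gave 4 and 0. Over all loci the split by number gave 1197 and 234. The untreated loci hold 92.8% of the loci of untreated replicate 2 and 35.5% of those of replicate 1, so choosing among them may favour number 2. The strongest loci in both TMPYP4 lists and neither PDS list were chromosome 5 at 52856405-52856650, chromosome 12 at 8395410-8395611, chromosome 9 at 6015456-6015762, chromosome 1 at 204380627-204381053 and chromosome 10 at 103347989-103348258. Over all loci, the counts for both lists of one compound and neither of the other were 271 and 6. At 1732 peaks per list they were 54 and 14. Such counts also depend on how far the 2 lists of a compound overlap. At that length the TMPYP4 lists shared 62.1% of peaks and the PDS lists 47.0%, so 54 against 14 may follow from that alone. The log2 ratio of peak numbers, TMPYP4 against PDS, was 0.80 (SE 0.45; 1.11 within number 1 and 0.49 within number 2), with an exact two-sided permutation p of 0.333; it was 0.37 without PDS replicate 1 and 1.23 without PDS replicate 2. The 271 became 1344 without TMPYP4 replicate 1, 1713 without TMPYP4 replicate 2 and 947 without PDS replicate 2; the 6 became 250 without PDS replicate 1, 412 without PDS replicate 2 and 14 without TMPYP4 replicate 1. Concentrations are not given in the sources used here.

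In the full lists, most of the loci missing after TMPYP4 were also missing after PDS. Both compounds lacked 635 loci, which is 87.2% of the 728 missing after TMPYP4 and 38.5% of the 1650 missing after PDS; 93 were missing after TMPYP4 only and 1015 after PDS only. Independent lists of these sizes would share 262.7 loci. Permuting presence in each treated list separately within deciles of untreated strength gave a mean of 469 and at most 511 over 1000 draws. These draws kept the number of loci in each list, but not the number missing from both lists of a compound. Both compounds were set against the same 2 untreated libraries, and a split would leave 1 library to each, so part of the excess may come from the shared controls. The draws also leave out any likeness of PDS and TMPYP4 libraries with the same replicate number. Without TMPYP4 replicate 2 both compounds lacked 1302 loci, against a mean of 1305 in the same draws, so no excess was seen there. Without PDS replicate 2 they lacked 726 against 724, of the 728 missing after TMPYP4, so an excess could hardly show. Leaving out a replicate 1 library kept the excess: 851 against 623 (untreated), 635 against 481 (PDS) and 744 against 534 (TMPYP4). Without untreated replicate 2 the count was 7732 against 6891. At 1732 peaks per list it was 23 of the 43 loci missing after TMPYP4, against a mean of 11.5 and at most 22.

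With each list reduced to its strongest 1732 peaks, the untreated libraries shared 75.0% of peaks, the TMPYP4 libraries 62.1% and the PDS libraries 47.0%. On chromosomes 1 to 22 and X only, with 1404 peaks per list, the PDS libraries shared 53.8%, untreated and PDS replicate 1 63.6%, and PDS and TMPYP4 replicate 1 72.4%. Libraries of the same group shared a mean of 61.4%, against 66.4% between groups, and 10 of the 15 ways to pair the 6 libraries gave a mean at least as high. Libraries of replicate number 2 shared 79.7% (untreated and PDS), 83.8% (untreated and TMPYP4) and 79.2% (PDS and TMPYP4). Those of number 1 shared 56.1%, 70.4% and 64.9% in the same order. Untreated replicate 1 shared 67.9% with PDS replicate 2 and 73.0% with TMPYP4 replicate 2, while untreated replicate 2 shared 51.7% with PDS replicate 1 and 64.1% with TMPYP4 replicate 1.

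**Figure D3:**
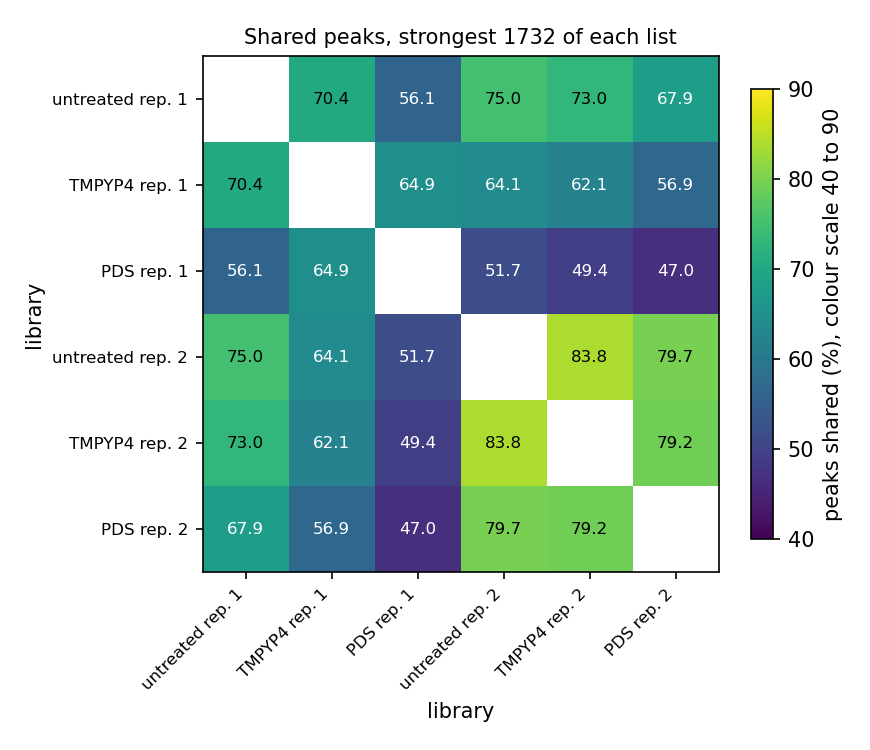
Percent of peaks shared (colour and printed value) by each pair of libraries (both axes), using the strongest 1732 peaks of each list, with libraries ordered by replicate number. Values run from 47.0% for the PDS libraries to 83.8% for untreated and TMPYP4 replicate 2.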

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

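The tests of explanations in this part were chosen after the results were seen. Signals outside the comparisons appeared in 3 places: 172 peaks of PDS replicate 1 on chromosome Y between 58819428 and 58917616, 87 peaks of the same library on the unplaced sequence chrUn_gl000220, and 826 loci of the combined untreated list (6.95% of its loci) in neither untreated list.

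Fewer untreated loci were listed after PDS and after TMPYP4, above all weak ones. These loci were chosen and ranked by the untreated lists, so a further untreated library could also miss some. Of the loci of untreated replicate 1, 35.5% were in untreated replicate 2, 31.5% in TMPYP4 replicate 2 and 22.6% in PDS replicate 2. Of those of untreated replicate 2, 92.8% were in untreated replicate 1, 43.2% in TMPYP4 replicate 1 and 22.2% in PDS replicate 1. Within replicate numbers the smaller log2 ratio of peak numbers was -0.69 for PDS and -0.19 for TMPYP4, which restates the pattern, so an effect of either compound stays open and untested. Lists of lower sensitivity could give the same: at equal length, untreated and treated lists of different numbers shared 59.8% (PDS) and 68.6% (TMPYP4), below the 75.0% of the untreated lists, while those of the same number shared 67.9% and 77.1%. The choice of pairs turns the comparison for TMPYP4, PDS lay lower on both means, and a noisier library also shares fewer strong peaks, so for both compounds lower sensitivity and treatment cannot be told apart without read depth. The median fold at like significance was 6.80, 6.81 and 6.80 in the untreated, PDS and TMPYP4 lists of number 2 and 5.41, 2.77 and 3.44 in those of number 1, and for TMPYP4 the split by number gave 753 loci in 1 pair only, against 728 for the real groups.

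Libraries of replicate number 2 resembled each other across treatments, and those of number 1 did so less. At equal list length, number 2 lists shared a mean of 80.9%, number 1 lists 63.8% and lists of different numbers 60.8%; untreated replicate 1 shared a mean of 63.2% with its own number, less than with the other. The division by number had a mean of 72.3%, the highest of the 10 divisions into 2 triples (66.8% for the next), a value carried by number 2. A batch shared by libraries of one number may be the source. The mark set for it after the results were seen was all 6 libraries closer to their own number, which held for 5. A batch could miss that mark, since untreated replicate 1 also has its treatment in common with untreated replicate 2 (75.0% shared). A batch thus stays open. No label says what the numbers stand for, and no biological explanation was tested.

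Peaks at repeats stood out in PDS replicate 1. The untreated and TMPYP4 lists had 0 peaks in the chromosome Y window and 0 to 4 on chrUn_gl000220, a sequence known to carry ribosomal DNA repeats. PDS replicate 2 had 3 peaks in the window and 0 on chrUn_gl000220, where all 3 libraries of number 2 had 0. PDS treatment thus stays open for both places. Every list held some peaks on chromosome Y, from 6 to 189. Whether the reads placed there came from chromosome Y or from repeats elsewhere was not tested. Reads of repeat sequences in PDS replicate 1 alone may also be the source. The 18.9% of its peaks off chromosomes 1 to 22 and X, against at most 1.17% elsewhere, includes the peaks in question, so it does not decide between these.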

How the results depend on the processing

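The overlap at equal length on chromosomes 1 to 22 and X and the counts between compounds were added after the data were seen. The count of loci missing after both compounds was planned under these settings, but its share was added later. Of 103 values under other settings, 62 stayed within tolerance, 41 moved beyond it and 0 reversed. Only log2 ratios could be labelled reversed, while counts and shares could only stay or move. The tolerance was the same direction for log2 ratios, 1.5 times for counts, and 1 SD for shares (25.9 points for PDS, 24.3 for TMPYP4, 14.0 for overlap at equal length). It is wide for shares: 20.5% for PDS against 7.31% without untreated replicate 2, or 33.8% with the replicate number as a block, fell within it. All log2 ratios of peak numbers kept their direction, but none could pass a threshold. With 1 library left out they ran from -2.47 to -1.12 for PDS, -1.67 to -0.31 for TMPYP4 and 0.37 to 1.23 for TMPYP4 against PDS. The groups did not overlap in list length, so leaving out 1 library could not change a direction. Only the stricter score and the limit to chromosomes 1 to 22 and X could have done so.

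Loci in both untreated lists and neither PDS list (1650) were 620 at a score of at least 82 and 87 at equal length; those for TMPYP4 (728) were 139 and 43. Loci in both PDS lists and neither untreated list (4) were 0 at that score, 1 on chromosomes 1 to 22 and X, 14 at 50% reciprocal overlap and 15 at equal length. The same count for TMPYP4 (0) was 38 at 50% reciprocal overlap and 31 at equal length. Shares in both treated lists rose to 56.9% (PDS) and 72.4% (TMPYP4) at equal length. Loci missing after both compounds were 23 at equal length. Loci of both TMPYP4 and neither PDS list were 54 at equal length; the reverse were 14, and 3 on chromosomes 1 to 22 and X. Shorter lists hold fewer loci by construction; for the other changes the cause was not tested.

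With 1 library left out, loci missing after PDS ranged from 1805 to 9635 and after TMPYP4 from 881 to 7909. Loci in treated lists only ranged from 4 to 444 (PDS) and 3 to 778 (TMPYP4), and shares in the treated lists from 7.31% to 60.5% and from 15.6% to 80.7%. Loci missing after both ranged from 635 to 7732, those of TMPYP4 and not PDS from 403 to 1713, and the reverse from 7 to 412. With fewer lists required, more loci qualify.

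With the replicate number as a block, the log2 ratios are by construction the same (-1.79, -0.99 and 0.80). Loci missing within a number averaged 6844 (PDS) and 5547 (TMPYP4), and loci in the treated list only 334.5 and 634.5. The replicate differences of the groups correlated across loci by 0.245, 0.203 and 0.416, but with 2 numbers this does not show that they pair the libraries. Promoter, quadruplex motif, YY1 motif and gene list settings were not run. Read depth, which would limit each list, is unknown.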

Other observations

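The chromosome, width and combined-list values in this part were chosen after the data were seen, and the p-values here are over loci within libraries, so they measure no spread between libraries. Loci of chromosome 7 were missing more often than loci of like untreated strength elsewhere in PDS replicate 1, with 120 of 132 missing against 103.2 expected (odds ratio 4.85, exact adjusted p = 9.86e-05). In the other treated libraries the odds ratios were 1.53 (PDS replicate 2), 1.79 and 1.64 (TMPYP4 replicates 1 and 2), with exact adjusted p of 0.235, 0.096 and 0.177. Of the 10 strongest loci in neither TMPYP4 list 4 were on chromosome 7, and of all 728 such loci 30 were, against 22.6 expected (odds ratio 1.59, exact adjusted p = 0.374). Loci of chromosome X were missing less often in TMPYP4 replicate 1, with 53 of 141 missing against 72.8 expected (odds ratio 0.365, exact adjusted p = 0.000483). In PDS replicate 1 the odds ratio was 0.586, and in the replicate 2 libraries it was 1.43 (PDS) and 1.17 (TMPYP4). These were the 2 of 92 tests of a chromosome and library with adjusted p under 0.05, and 22 had an unadjusted p under 0.05. Over loci missing from both libraries of a compound, 0 of 46 exact chromosome tests passed after adjustment, and 6 had an unadjusted p under 0.05; the lowest was chromosome 7 with PDS, 63 loci against 49.8 expected (odds ratio 1.85, adjusted p = 0.238).

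Wide untreated loci were missing less often than narrow loci of like strength in all 4 treated libraries. The odds ratios for loci wider than the median of 249.5 bp were 0.351 in PDS replicate 2 and 0.349 in TMPYP4 replicate 2 (exact adjusted p = 1.34e-42 and 2.75e-25). In PDS replicate 1 and TMPYP4 replicate 1 they were 0.806 and 0.835, each with an exact adjusted p of 0.0338.

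The combined untreated list held 12063 peaks. Of its loci, 92.3% were in untreated replicate 1 and 38.6% in untreated replicate 2, and 756 were in none of the 6 library lists.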
